A study of Methylococcus capsulatus str. Bath with 15 samples.

How the data were processed

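RNA sequencing libraries were made from Methylococcus capsulatus strain Bath, a methanotroph, that is, a bacterium that lives on methane. Per the labels' protocols, AMS medium was inoculated to an optical density of 0.03 under a headspace of 50% methane and 50% air at 2 atm, and cultures were shaken at 200 rpm and 37 °C. Hydrogen sulfide (H2S), a toxic gas, was added to the headspace at 0.1%, 0.5% or 0.75% for growth. For the shock, H2S was added to a growing control culture at an optical density near 0.6, and the cells were collected 1 h later. The concentration used for the shock is not given in the sources used here. RNA was extracted near an optical density of 0.8 with a column kit and sequenced on Illumina instruments, per the labels' protocols, which give the molecule as polyA RNA.

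The deposited data are 2 tables of 3020 genes by 15 libraries. One holds raw whole-number counts of reads per gene, which the authors made with no normalization. The other holds deposited log2 CPM, the reads of a gene scaled to a common library total. Its values were recomputed from the counts with edgeR's trimmed mean of M values (TMM) scaling and a prior count of 2, and the largest difference was 5e-09. The log2 table was used for this check alone. Per the submitters' processing notes, Trimmomatic, BWA, SAMtools, featureCounts and edgeR were used. Their versions and settings, the genome build, the annotation and whether counting used strand are not given in the sources used here. Reads from overlapping genes, antisense genes or near-identical copies can therefore be split in ways that cannot be checked here.

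Every column was matched to its library through the labels, giving 5 groups of 3 libraries, and 0 columns of values were left unmatched. The labels number the libraries but do not say whether those of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicates were compared by a chi-square test of their counts. The statistic per degree of freedom was 124.7 or more for every pair within a group, so no library was treated as a duplicate.

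The test, the samples in each fit, the alternatives and the rule for named genes were fixed before the data were examined. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with edgeR's default low-count filter by group, TMM scaling and robust dispersion. All 15 libraries entered 1 fit with a mean per group, which left 10 residual degrees of freedom. The filter removed 6 genes and left 3014. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A linear trend over concentration was fitted to the 12 growth libraries, with control taken as 0, on the 3012 genes that passed the filter there. Levels are given as CPM, mean ± SD over 3 libraries, and differences as log2 fold changes with their standard error (SE).

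The method was tested on simulated counts with known changes, planted in 50 genes per size of change and in 100 genes per slope. In the comparison of 0.75% H2S with control, over 3014 genes, 16% of the genes changed 1.5-fold were called, 56% of those changed 2-fold, 82% of those changed 4-fold and 94% of those changed 8-fold. Of 129 calls, 5 were false. In the comparison of the shock with control, over the same number of genes, the shares were 10%, 46%, 84% and 88%, and 10 of 124 calls (8.06%) were false. For the trend, slopes are in log2 units per percentage point. Of the genes with a slope of 2, 78% were called, and of those with a slope of 4, 91%. Of 180 calls, 11 were false. The data gave 24 calls at 0.75% H2S and 6 for the trend, fewer than in simulation. The cut on unadjusted p is then stricter, so these shares may overstate the power in the data. The shock gave 623 calls, more than in simulation. The data also held a gap in low counts, described below, that the fitted negative binomial model lacked. The numbers of false calls may therefore not carry over to the data.

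Comparisons against control share the same 3 control libraries, so overlaps of calls and covariances of fold changes are given beside the values from 100 simulated sets in which no group differed from control. For genes selected in 1 growth comparison, 100 further sets gave that group its fitted changes and left the other growth groups at control, a simulation added after the data were seen. Fitted changes hold the noise of the libraries themselves, so these sets may understate what shared libraries carry over. The controls are too few to be split into sets of at least 2 libraries. The alternatives were median-ratio size factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter of 10 CPM in 3 libraries, fits of only the groups compared, a replicate block, a 2-fold minimum and leaving out each library in turn. For the trend, the rank of the concentration was also used. Alternatives added after the data were seen were random thinning of reads to the smallest library, counts divided by an estimated number of reads per unit, the same units thinned to the smallest library, a fit without control 2 and 0.1% H2S 2, and scaling by library totals alone.

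The files give gene IDs and do not pair them with names or products. The 34 gene lists fixed by product, symbol or older locus tag could not be matched to IDs, so no list was tested, and the alternative without ribosomal and transfer RNA genes was not run. The fixed rule for named genes would have taken list members and the 7 largest rises and 7 largest falls in each comparison with control, the latter among called genes with a mean count of at least 50 and no overlap between the groups. It was reduced to the largest rise and the largest fall of each comparison, after the values had been seen, because at most 4 IDs without names are given here. The reduced rule gives exactly 4 genes. Where a gene had 0 reads in a whole group, its fold change is given as a bound from a floor of 3 counts per library. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.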

Results

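The transcript levels of M. capsulatus Bath were measured in 5 groups of 3 libraries: control cultures, cultures grown at 0.1%, 0.5% or 0.75% H2S in the headspace, and control cultures given an H2S shock for 1 h before collection. The series addresses the toxicity of H2S to this organism. Total counts ran from 7487670 in shock 1 to 46414724 in 0.75% H2S 2. Group means were 27300000 ± 12140000 reads in control, 23570000 ± 5172000 at 0.1% H2S, 28890000 ± 2379000 at 0.5%, 30040000 ± 14710000 at 0.75% and 12840000 ± 4879000 in the shock (SD, n = 3 each). The shock libraries were thus the shallowest group on average, and held the most genes without a read, 112 ± 10.2 of 3020 against 54 ± 38.1 in control.

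The shock libraries lay apart from the others on the first principal component. On this principal component of log2 CPM, which held 25.2% of the variance, the shock libraries lay at 40.7, 56.9 and 45.6, and each of the other 12 libraries lay at -3.35 or below. The second component held 13.3% of the variance and set apart control 2 (-32.5), 0.1% H2S 2 (-28.2) and shock 1 (-40.4) from the other members of their groups. Each of these had the fewest reads in its group and the most genes without a read (98, 109 and 119). Whether read depth lies behind the second component was not tested. The mean Pearson correlation across genes between libraries of a group was 0.903 in control, 0.884 at 0.1% H2S, 0.896 at 0.5%, 0.928 at 0.75% and 0.835 in the shock, and shock libraries correlated with those of control at 0.830, of 0.1% H2S at 0.801, of 0.5% at 0.819 and of 0.75% at 0.839, the last no lower than among themselves. Genes are not independent replicates, and these correlations carry no test.

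**Figure D1:**
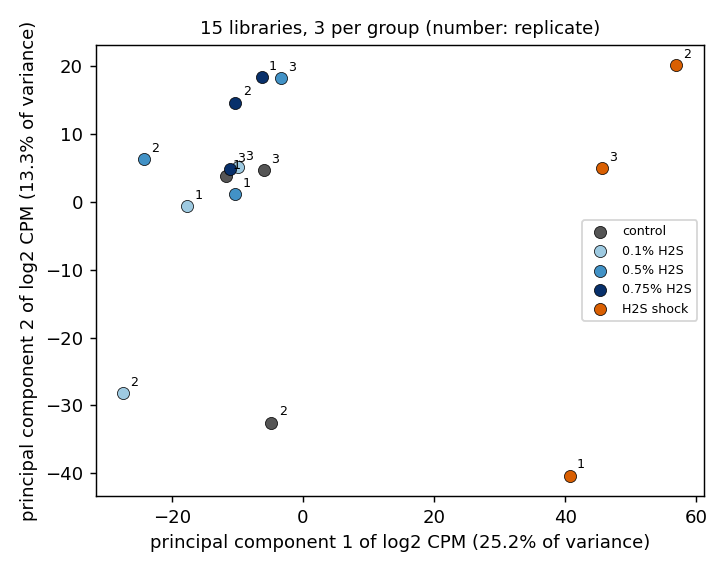
Positions of the 15 libraries on the first and second principal components of log2 CPM, in arbitrary units, with colour giving the group and the number beside each point the replicate. The shock libraries lie at 40.7 or above on the first component, and control 2, 0.1% H2S 2 and shock 1 lie at -28.2 or below on the second.

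Growth at 0.1% H2S against control asked which genes respond to the lowest concentration. By edgeR a single gene, MCA_RS05830, rose. Its level was 35.4 ± 12.1 CPM in control and 261 ± 41.5 CPM at 0.1% H2S (SD, n = 3), a 7.38-fold rise (log2 fold change 2.88, SE 0.269, adjusted p = 1.28e-05, edgeR quasi-likelihood test). All 3 libraries at 0.1% lay above all 3 controls, which the rule for named genes required. EdgeR called 0 genes lower. At an unadjusted p under 0.05 there were 184 genes of 3014. DESeq2 called 25 genes, 17 higher and 8 lower, and limma-voom 11, all higher, each including this gene. Without 0.1% H2S 1, edgeR called 1 gene higher and 1 lower.

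At 0.5% H2S, edgeR called 7 genes higher and 0 lower against control. MCA_RS05830 again had the largest rise, to 234 ± 9.14 CPM, 6.65-fold above control (log2 fold change 2.73, SE 0.267, adjusted p = 2.64e-05, edgeR). Of the 7 genes, 6 rose at least 2-fold. The same 7 genes had a median log2 fold change of 1.39 at 0.1% H2S, where 1 of them was called and 6 were not, and 1.74 at 0.75%, where all 7 were called. Simulated sets, 100 in all, took the fitted changes at 0.5% as true. Genes selected in them had a median of 0.153 at 0.1% (highest 0.442) and 0.169 at 0.75% (highest 0.425). The sets selected 15.2 genes on average, against 7 in the data. Fitted changes already hold the noise of the controls, so these sets may understate what the shared controls carry over. They do not settle how much the 7 genes responded at 0.1%. At an unadjusted p under 0.05 there were 116 genes, DESeq2 called 22 genes, 17 higher and 5 lower, and limma-voom 12, all higher. With estimated units edgeR called 12 higher and 1 lower, and without 0.5% H2S 2 it called 7 higher and 1 lower. Leaving out control 1, control 3 or 0.5% H2S 3 gave 3 genes, and leaving out 0.5% H2S 1 gave 4. Leaving out shock 1, which enters the shared estimate of spread, gave 11.

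At 0.75% H2S, edgeR called 23 genes higher and 1 lower against control. MCA_RS05830 reached 302 ± 30.5 CPM, 8.51-fold above control (log2 fold change 3.09, SE 0.271, adjusted p = 5.08e-06, edgeR). The largest rise was that of MCA_RS05425, from 12.2 ± 4.01 CPM in control to 126 ± 48.1 CPM (log2 fold change 3.38, SE 0.676, adjusted p = 0.0394). The gene that fell was MCA_RS12640, from 210 ± 38.2 CPM in control to 84.8 ± 11.3 CPM, or 2.46-fold (log2 fold change -1.30, SE 0.199, adjusted p = 0.00199). At 0.1% and 0.5% H2S its levels were 194 ± 26.2 and 185 ± 19.5 CPM, neither of which differed from control by the test (adjusted p = 0.968 and 0.999). Of the 24 genes, 21 changed at least 2-fold, 20 of them upward. DESeq2 called 42 genes higher and 12 lower, limma-voom 35 and 5, and the edgeR fit of only these groups 38 and 10.

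The call of MCA_RS05425 at 0.75% H2S was lost in 16 of 28 alternatives, over which its log2 fold change ran from 3.02 to 3.64 and its adjusted p from 3.96e-08 to 0.546. Leaving out any 1 control library or any 1 library at 0.75% ended it. The call of MCA_RS12640 was lost when the counts were expressed as estimated units and thinned to the smallest library (log2 fold change -0.85, adjusted p = 0.183, with a range of 2.65e-07 to 0.183 over its alternatives). The count of 24 genes became 9 without control 1 or control 3, 13 without control 2, and 11 without 0.75% H2S 1 or 2. Without both control 2 and 0.1% H2S 2, which lie apart on the second principal component, it was 13, all among the 24.

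**Figure D2:**
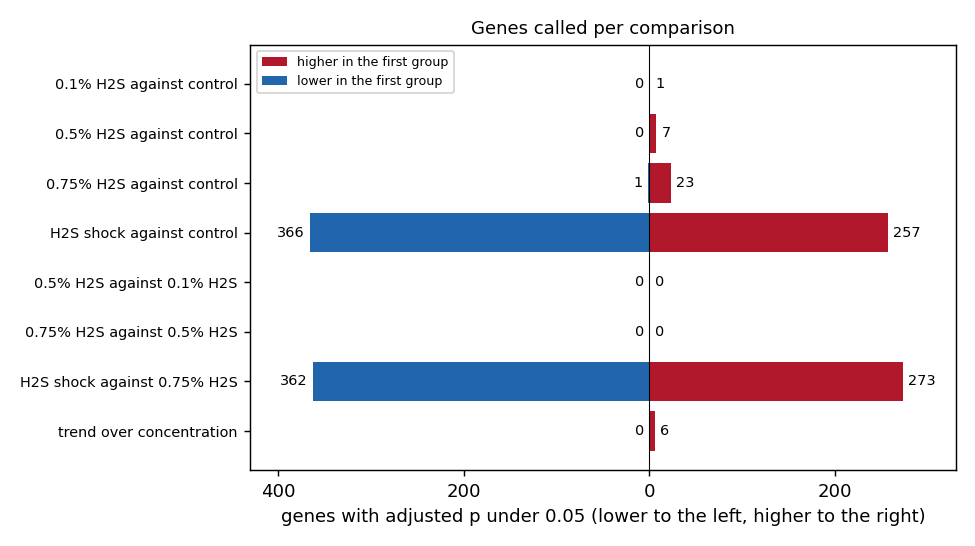
Number of genes with an adjusted p under 0.05 in each comparison, with genes lower in the group named first to the left of 0 and genes higher to the right; for the trend, right means rising with concentration. The shock changed 623 genes against control, and growth changed 1 gene at 0.1% H2S, 7 at 0.5% and 24 at 0.75%.

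The direct contrasts asked whether adjoining concentrations differ. Between 0.5% and 0.1% H2S, edgeR called 0 genes (smallest adjusted p 0.378, 139 genes at an unadjusted p under 0.05), DESeq2 called 13 and limma-voom 0. Between 0.75% and 0.5% H2S, edgeR called 0 genes (smallest adjusted p 0.0663, 120 genes at an unadjusted p under 0.05), DESeq2 called 7 and limma-voom 3. The smallest adjusted p of the second contrast was that of MCA_RS12640, which was 2.20-fold lower at 0.75% than at 0.5% (log2 fold change -1.14, SE 0.199) and was called by DESeq2 (adjusted p = 0.000382) and limma-voom (adjusted p = 0.0355). For MCA_RS05830 the log2 fold change was -0.15 (SE 0.25, adjusted p = 0.981) from 0.1% to 0.5% and 0.36 (SE 0.25, adjusted p = 0.998) from 0.5% to 0.75%, and neither passed the test. The 23 genes raised at 0.75% had median log2 fold changes of 0.97 at 0.1% H2S, 0.999 at 0.5% and 1.74 at 0.75% against control. Simulated sets, 100 in all, took the fitted changes at 0.75% as true. Genes selected in them had a median of 0.136 at 0.1% (highest 0.309) and 0.138 at 0.5% (highest 0.266). The sets selected 45.8 genes on average, against 23 in the data. Fitted changes already hold the noise of the controls, so these sets may understate what the shared controls carry over. They do not settle how much the 23 genes responded at 0.1% and 0.5%. All 23 had higher fitted values at 0.75% than at 0.5%, but they were selected at 0.75%. In that contrast edgeR called 0 of them (8 at an unadjusted p under 0.05), DESeq2 4 and limma-voom 2.

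The linear trend asked which genes have a slope over concentration in the 12 growth libraries. EdgeR called 6 genes, all rising, with a median slope of 2.68 log2 units per percentage point of H2S. A slope does not by itself show a steady rise. Against control the 6 genes had median log2 fold changes of 0.494 at 0.1% H2S, 0.868 at 0.5% and 2.18 at 0.75%. At 0.1%, 4 of the 6 values were positive, and the lowest was -0.355. The median step was 0.594 from 0.1% to 0.5% and 1.22 from 0.5% to 0.75%. MCA_RS05425 was among them, at 12.2 ± 4.01 CPM in control, 27.99 ± 9.15 at 0.1% H2S, 71.8 ± 23.03 at 0.5% and 126 ± 48.1 at 0.75% (slope 4.07, SE 0.490, adjusted p = 0.000613). Its trend call held in all 23 alternatives that gave it a value. MCA_RS05830, which was already 7.38-fold higher at 0.1% H2S, did not pass the trend test (slope 1.89, SE 0.981, adjusted p = 0.482). Of the 6 genes, 5 were also called at 0.75% H2S against control. At 0.5%, edgeR called 0 of the 6 (3 at an unadjusted p under 0.05), DESeq2 1 and limma-voom 0. The count depended on single libraries: it was 37 without 0.5% H2S 2 (30 rising and 7 falling), 11 without 0.1% H2S 3, 3 without 0.1% H2S 1 or 0.75% H2S 1, 2 without control 1 or control 3, and 1 without 0.75% H2S 2. DESeq2 called 81 genes, 51 rising and 30 falling, and limma-voom 11, 10 rising and 1 falling.

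**Figure D3:**
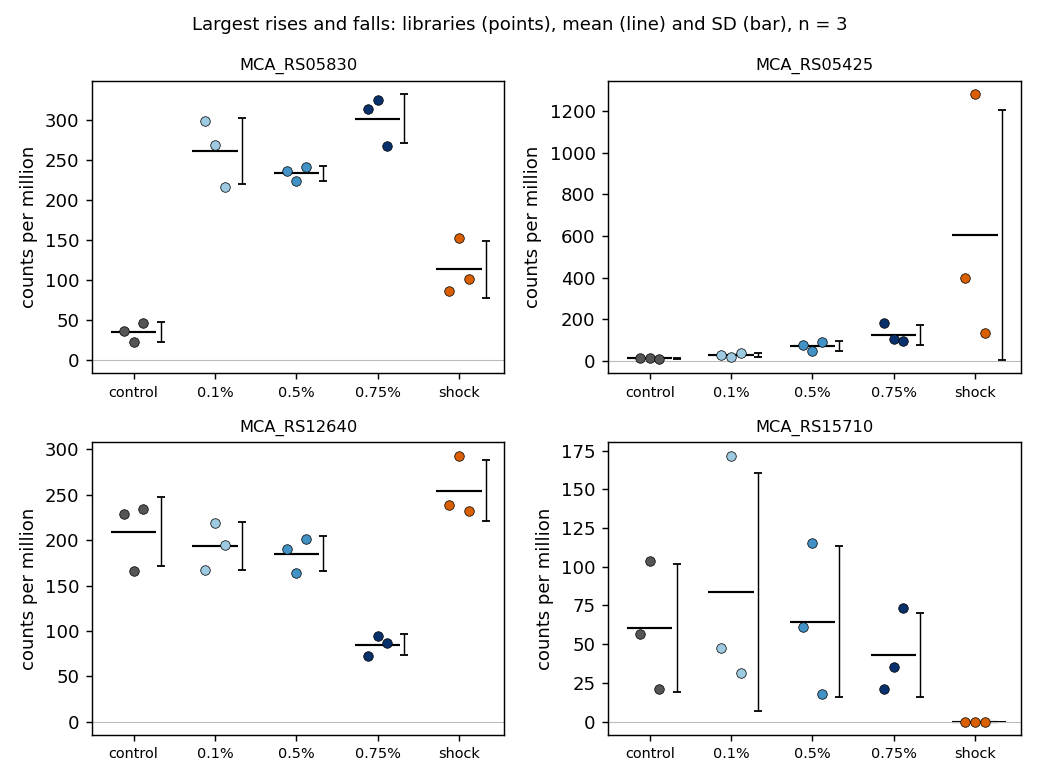
CPM of the 4 named genes in each of 5 groups, on linear axes, with a point per library, a line at the mean and a bar for the SD (n = 3). MCA_RS05830 is higher in all 12 H2S libraries than in any control, MCA_RS12640 is lower at 0.75% H2S than in every other group, and MCA_RS15710 has 0 reads in all 3 shock libraries.

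The shock for 1 h changed far more genes than growth at any concentration. Of 3014 genes, 257 rose and 366 fell, 20.7% in all by edgeR, against 24 at 0.75% H2S. The larger number of falls was not kept by limma-voom, which called 216 genes higher and 208 lower; DESeq2 called 297 higher and 415 lower. At least 2-fold, 50 rose and 226 fell. MCA_RS05425 had the largest rise under the rule for named genes, to 604 ± 600 CPM, 50.3-fold above control (log2 fold change 5.65, SE 0.749, adjusted p = 0.000422, edgeR). Its libraries differed widely, at 396, 1280 and 135 CPM, and all 3 lay above the controls, which the rule for named genes required. The log2 fold change ran from 4.47, without shock 2, to 6.13, without shock 3, and the call held in all 28 alternatives (highest adjusted p 0.0448). MCA_RS05830 also rose, to 114 ± 35.2 CPM or 3.24-fold (log2 fold change 1.70, SE 0.258, adjusted p = 0.000387). MCA_RS12640, the gene that fell at 0.75% H2S, stood at 255 ± 33.6 CPM in the shock and did not differ from control by the test (log2 fold change 0.30, SE 0.196, adjusted p = 0.308).

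MCA_RS15710 had no read in any of the 3 shock libraries, against 60.5 ± 41.5 CPM in control, 83.6 ± 76.7 at 0.1% H2S, 64.6 ± 48.9 at 0.5% and 43.1 ± 27.0 at 0.75%. With a floor of 3 counts per library its level in the shock was at least 226-fold lower than in control (adjusted p = 0.000621, edgeR). This bound became 145-fold without control 2, and ran from 192-fold to 318-fold without any 1 of the other control and shock libraries. The floor covers the counting of reads alone. In the shock libraries the estimated reads per unit ran from 67.9 to 141.6, so a floor of 3 reads is far under 1 unit. A floor of 3 units would give a far smaller bound. Low counts in these libraries tend to skip from 0 to well above 10 reads, and the call was lost in 3 alternatives. The fitted log2 fold change, which is no bound for a gene without reads, was -13.54 (SE 1.84) as reported. It was -7.087 (SE 3.1, adjusted p = 0.137) with counts divided by the estimated reads per unit, -5.751 (SE 1.89, adjusted p = 0.0502) with those units thinned and -9.94 (SE 8.33, adjusted p = 0.454) in limma-voom. The adjusted p ranged from 4.61e-15 to 0.454 over its alternatives.

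Abundant genes were called more often in the shock, but not in the shock alone. In the least abundant of 4 equal classes of genes by mean log2 CPM, 6.23% were called, with 9 higher and 38 lower. In the most abundant class, 33.2% were called, with 134 higher and 116 lower. At 0.75% H2S against control the shares were 0.133% and 1.46%, and in the trend 0.265% and 0. A test has more power with more reads, so these shares do not show that abundant genes responded more often. Of the 50 most abundant genes, 5 rose and 9 fell, while 0 of the 10 most abundant genes were called in the shock by edgeR, DESeq2 or limma-voom, or had an unadjusted p under 0.05. Those 10 genes took 17.2 ± 1.1% of the counts in the shock and 15.98 ± 0.912% in control. Their highest share was in 0.5% H2S 3, at 22.27%, against 13.69% in 0.5% H2S 1 and 12.45% in 0.5% H2S 2, so that library was unlike its group. The count of 623 became 394 without control 1, 378 without control 2, 389 without shock 2, and 370 without control 2 and 0.1% H2S 2, of which 353 were among the 623.

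The last comparison asked whether the shock and growth at 0.75% H2S differ from each other. The test of that difference called 635 genes, 273 higher and 362 lower in the shock (994 genes at an unadjusted p under 0.05). Of the 257 genes raised by the shock against control, 159 were also higher than at 0.75%, and of the 366 lowered, 275 were also lower than at 0.75%. The 257 and 366 genes were selected in the same shock libraries, so agreement in direction is partly built in. No simulated value was made for them. Of the 23 genes raised by growth at 0.75%, 6 rose, 4 fell and 13 were not called in the shock against control, and 19 were lower in the shock than at 0.75%. These 23 genes were selected for high values in the same libraries at 0.75%. In simulated sets a mean of 0.0349% of such genes (highest 1.85%) were called lower if the shock equalled growth at 0.75%. The mean was 69.2% (highest 88.9%) if the shock equalled control. The sets took the fitted changes as true, so they may understate the effect of the selection. MCA_RS05830 was 2.63-fold lower in the shock than at 0.75% (log2 fold change -1.39, SE 0.255, adjusted p = 0.00141, edgeR). MCA_RS12640 was 3.03-fold higher (log2 fold change 1.60, SE 0.201, adjusted p = 7.85e-05). MCA_RS05425 was 4.85-fold higher (log2 fold change 2.28, SE 0.640, adjusted p = 0.0257), but this call was lost in 6 of 28 alternatives, including those without shock 2 (log2 fold change 1.09, adjusted p = 0.12), 0.75% H2S 2 or 0.75% H2S 3. The count of 635 became 341 without 0.75% H2S 3 and 391 without shock 2. Scaled by library totals alone it was 575, with 183 higher and 392 lower. By limma-voom it was 494, with 266 higher and 228 lower, so that the direction of the majority depended on the tool.

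**Figure D4:**
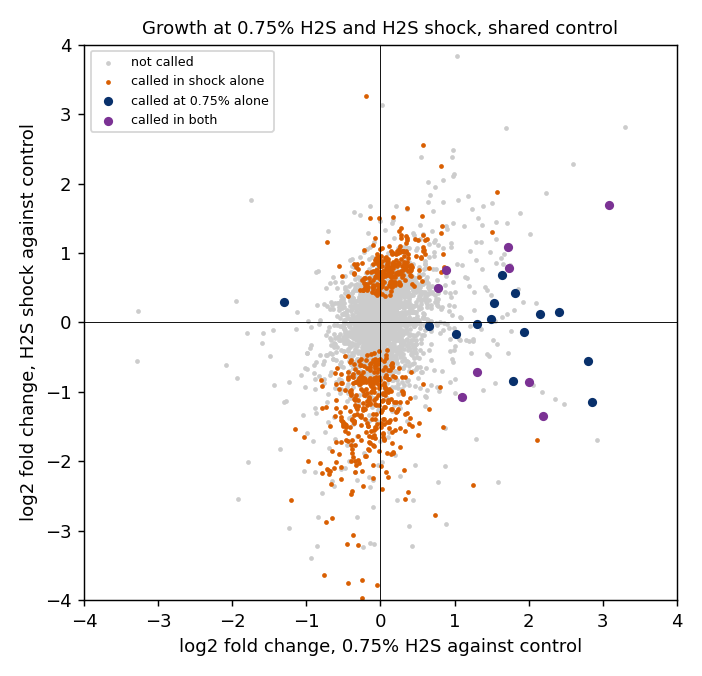
Log2 fold change of each gene at 0.75% H2S (horizontal) and in the shock (vertical) against the shared control, coloured by the comparison in which the gene was called. The axes end at 4 in each direction and leave 37 genes outside; 10 genes were called in both comparisons, 6 of them higher in both and 4 higher at 0.75% and lower in the shock, against 14 at 0.75% alone and 613 in the shock alone.

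All comparisons with control share the same 3 libraries, so their overlaps were set beside simulated and independent values. The 7 genes raised at 0.5% H2S were all raised at 0.75%, where independent lists would share 0.0534 genes and simulated unchanged groups shared 0 in all 100 sets. Growth at 0.75% and the shock shared 6 raised genes, against 1.96 for independent lists and a mean of 0.02 in simulated sets. The simulated sets leave out all effects and so call few genes, and independent lists leave out the shared controls, so an excess over either is not evidence of a shared effect. The 4 genes called in opposite directions were higher at 0.75% and lower in the shock. With DESeq2, 0.5% and 0.75% shared 19 genes and 0.75% and the shock 16, and with a 2-fold minimum the latter shared 3. The covariance of log2 fold changes across genes was 0.296 between 0.5% and 0.75% (simulated mean 0.182, highest 0.234) and 0.239 between 0.75% and the shock (simulated mean 0.182, highest 0.240), the latter within the simulated range. For 0.1% H2S it was 0.245 with 0.5% (simulated highest 0.219), 0.241 with 0.75% (simulated highest 0.220) and 0.107 with the shock (simulated mean 0.179). The correlation, which does not grow with the spread of fold changes, was 0.666 between 0.5% and 0.75% (simulated mean 0.503). Between 0.1% and 0.5% it was 0.536 (simulated mean 0.502). Between 0.1% and 0.75% it was 0.47 (simulated mean 0.499), so the correlation showed no excess there, although the covariance did. Changes particular to 1 group lower a correlation, so the 2 measures can differ and do not settle this. Shock fold changes correlated at 0.134 with 0.1%, 0.213 with 0.5% and 0.308 with 0.75%, against simulated means of 0.496, 0.497 and 0.499. The simulated groups have no changes of their own, whereas many genes changed in the shock, which lowers a correlation by itself. These lower values therefore do not show that the shock is unrelated or opposed to growth. Part of any excess may come from the shared controls, which are too few to be split.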

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

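Among the tests below, those that thinned reads to the smallest library and those that used estimated units were chosen after the data were seen.

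The shock and growth at 0.75% H2S differed in their change against control for 635 genes, by a direct test of the difference (edgeR). Among these, 4 genes rose at 0.75% H2S and fell in the shock, with log2 fold changes of 1.31 and -0.71, 2.01 and -0.86, 1.11 and -1.07, and 2.19 and -1.35. The difference between shock and 0.75% H2S was -1.393 on the log2 scale for MCA_RS05830, 2.277 for MCA_RS05425 and 1.601 for MCA_RS12640, each past the threshold in the test of the difference. The value of MCA_RS05425 no longer passed the threshold without shock 2, where it was 1.09 (adjusted p = 0.12), nor without 0.75% H2S 2 (2.15, adjusted p = 0.0856) or 0.75% H2S 3 (2.11, adjusted p = 0.099), in a range of 0.000175 to 0.12 over its alternatives.

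The first pattern weighed is the large number of genes called in the shock, 623, against 1, 7 and 24 in growth. Lower read depth is argued against as the whole cause, since with every library thinned to 7487670 reads the shock called 605 genes and growth 1, 7 and 26. Fewer template molecules are argued against in the same way: with estimated units thinned to the smallest library the shock called 369 genes and growth 4, 7 and 22, although this count is well under 623. The unit is estimated from genes without reads, judged against all other libraries. Genes silenced by the shock would thus count as missing units, so this setting is not independent of the response. A shift of library totals by a few genes is argued against by scaling with library totals alone. There the median log2 fold change of all genes in the shock was -0.0158. The shock then called 588 genes and growth 3, 6 and 25. The other scalings centre most genes near 0 and decide nothing here. No scaling used can show a change in total RNA per cell. What stays open is an unlabelled difference in when or how the 3 shock libraries were made, which the design confounds with the treatment, and the treatment itself, which differed from growth in duration and possibly in concentration.

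Other groupings of the libraries were tested for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1 gene at 0.1% H2S, 7 at 0.5%, 24 at 0.75%, 623 in the shock and 635 for the shock against 0.75%, and the highest of the other splits gave 0, 0, 0, 5 and 0, so that 1 of 10 splits was as large in each. Between 0.75% and 0.5% H2S the real split and the highest other both gave 0, and all 10 were as large. Between 0.5% and 0.1% H2S the real split gave 0 and another gave 107, so all 10 were as large. The split with 107 genes set 0.5% H2S 1, 0.5% H2S 3 and 0.1% H2S 3 against the rest. It was the highest of the other splits, whose median was 0. Whether it reflects a structure of the samples that the labels do not name was not tested. For the trend, 3 of 100 assignments of the 12 libraries to concentrations, the real one included, gave as many as 6 genes. The share is under 0.05, but its exact 95% interval of 0.623% to 8.52% spans that bound, so chance is not excluded. The highest other assignment gave 169 genes, against a median of 0. Whether a structure of the samples other than concentration lies behind it was not tested.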

How the results depend on the processing

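The settings added after the data were seen were read thinning, estimated units, units thinned, the fit without control 2 and 0.1% H2S 2, and library totals alone. The alternative without ribosomal and transfer RNA genes and all gene-list tests were not run, because IDs could not be matched to products. Over the comparisons, 156 alternative counts of called genes lay within 1.5 times the reported count and 65 did not. The cause of each change below was not tested. A fold minimum can only lower a count, whereas leaving out a library raised some counts and lowered others.

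At 0.1% H2S, where 1 gene was called, DESeq2 gave 25, limma-voom 11, the fit of only those groups 5, estimated units 10, units thinned 4, library totals alone 3 and the fit without control 2 and 0.1% H2S 2 gave 2. Leaving out single libraries gave 1 to 5, with 5 without shock 1, shock 2 or 0.5% H2S 3, 4 without control 2, 3 without 0.5% H2S 2, and 2 without shock 3, 0.1% H2S 1 or 0.1% H2S 3. At 0.5% H2S (7 genes) DESeq2 gave 22, limma-voom 12, estimated units 13 and single libraries left out 3 to 11. At 0.75% H2S (24 genes, 95.8% higher) DESeq2 gave 54 (77.8% higher), limma-voom 40, the fit of only those groups 48 (79.2% higher), estimated units 43, the fit without control 2 and 0.1% H2S 2 gave 13, and single libraries left out gave 9 to 30. For the shock against control (623 genes) the 2-fold minimum gave 276, units thinned 369, the fit without control 2 and 0.1% H2S 2 gave 370, and single libraries left out 378 to 689; DESeq2 gave 712 (41.7% higher) and limma-voom 424 (50.9% higher, against 41.3%). Between 0.5% and 0.1% H2S (0 genes) DESeq2 gave 13. Between 0.75% and 0.5% H2S (0 genes) DESeq2 gave 7, limma-voom 3, estimated units 6 and single libraries left out 0 to 1, with 1 without control 2 or 0.75% H2S 3. For the shock against 0.75% H2S (635 genes) the 2-fold minimum gave 276, units thinned 382 and single libraries left out 341 to 696; limma-voom gave 494 (53.8% higher, against 43%). For the trend (6 genes) DESeq2 gave 81, limma-voom 11, estimated units 25, units thinned 8 (1 of them among the 6), library totals alone 14, the rank of the concentration 27, the fit without control 2 and 0.1% H2S 2 gave 2, and single libraries left out 1 to 37.

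Whether the replicate numbers pair the libraries stays open. Of 30 same-number pairs, 2 had deviations correlated above 0.1 (range -0.168 to 0.221). For 8 of 15 libraries the closest library of another group had their own number. These values were not set beside chance values, so a pairing is neither shown nor excluded. With the replicate block the counts were 2 at 0.1% H2S, 14 at 0.75% and 3 for the trend, while the others lay within 1.5 times. Under the block MCA_RS05425 lost its calls at 0.75% H2S (adjusted p = 0.0991) and for the shock against 0.75% (adjusted p = 0.0592), and no other call of a named gene changed.

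Over the alternatives for the 4 named genes, 826 values stayed on their side of the threshold with their sign, 29 called values lost the call, 10 gained one and 14 changed sign. No called value changed sign. Below, reported values stand in parentheses, and "from" or "to" marks the far end of the range over single libraries left out. The 14 had adjusted p of 0.929 or more. For MCA_RS12640 from 0.1% to 0.5% H2S (-0.05) they were 0.05209 without control 2 and 0.1% H2S 2, 0.0521 without 0.1% H2S 2 and 0.03053 without 0.5% H2S 2 (single libraries left out: -0.1578 to 0.0521). For MCA_RS15710 against control they were -0.6076 at 0.1% (0.47) without 0.1% H2S 2 (to 1.117), -0.2988 and -0.6137 at 0.5% (0.11) without control 3 and 0.5% H2S 2 (to 0.7559), and 0.1614 at 0.75% (-0.48) both without control 2 (from -1.101) and without the pair. From 0.1% to 0.5% (-0.36) they were 0.04315 with estimated units, 0.7179 both without the pair and without 0.1% H2S 2, and 0.07496 without 0.5% H2S 3 (from -1.085). From 0.5% to 0.75% (-0.59) the value was 0.1297 without 0.5% H2S 2 (from -1.212), and the trend slope (-0.82) was 0.4665 without the pair. MCA_RS05830 kept its call and direction in all 28 alternatives at each concentration and in the shock.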

Other observations

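The longest runs of called genes in adjacent rows of the table, and the tests on adjacent rows and on the gap in low counts named below, were looked at after the data were seen; the tests of rows 3 apart and of control pairs in the shock were written before their results, and the pairs of libraries of the other groups, the resampled rows and the reading of 0.5% H2S alone were added later.

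A run of 17 adjacent rows fell together in the shock. Its genes were abundant, with a median of 840 CPM in control, and their log2 fold changes in the shock ran from -2.55 to -0.65 with a median of -1.48 (largest adjusted p 0.0474, edgeR). In growth edgeR and limma-voom called 0 of the 17, with median log2 fold changes of 0.13 at 0.1% H2S, -0.36 at 0.5% and -0.60 at 0.75%. At 0.75%, 10 of them had an unadjusted p under 0.05 and DESeq2 called 1. In the trend over concentration, edgeR and limma-voom called 0 of the 17 (15 at an unadjusted p under 0.05) and DESeq2 9. Against growth at 0.75% H2S, 10 of the 17 were lower in the shock. A run of 5 adjacent rows rose at 0.75% H2S, with a median log2 fold change of 1.64. The median was 1.43 at 0.5%, where edgeR called 3, and 1.12 at 0.1%, where edgeR called 0 and DESeq2 and limma-voom 4 each (all 5 at an unadjusted p under 0.05). In the shock 2 of these 5 rose and 1 fell, and 4 of them were lower than at 0.75%.

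The second pattern weighed is that genes in adjacent rows moved together: Spearman's rho of log2 fold changes against control between adjacent rows was 0.290 in the shock, 0.226 at 0.1% H2S, 0.171 at 0.5% and 0.309 at 0.75%, against at most 0.0733 in 1000 shuffles of the rows of each. Reads that span 2 neighbouring genes are argued against as the whole cause by rows 3 apart in the shock, at 0.1% and at 0.75%, where rho was 0.124, 0.0773 and 0.186 against at most 0.0546, 0.0523 and 0.0646 in shuffles; at 0.5% it was 0.062 against 0.0693, while rows 2 apart gave 0.108 against 0.0497, and the cause cannot be told apart. Noise shared by neighbours was read from the differences between 2 libraries of one group, at most 0.124 in control: rho exceeded the highest pair of the libraries compared in the shock (0.143; 95% interval of the difference 0.0931 to 0.19, blocks of rows resampled) and at 0.75% (0.186; 0.0673 to 0.176), which argues against it there, while it stays open at 0.1% (0.209; -0.0392 to 0.0676) and would be enough at 0.5% (0.329; -0.227 to -0.0995). For the shock a candidate explanation is that neighbouring genes are regulated together, as in an operon: 268 of 623 genes called in the shock lay beside another called gene of the same direction, against a mean of 125 and a highest of 174 in shuffles. The hypothesis came from these data, a difference in how the shock libraries were made stays open, and a link between table order and gene position was not tested here.

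The third pattern weighed is a gap in the counts. Of 44108 values of a gene in a library with at least 100 reads expected, 349 were 0 and 31 were 1 to 10, whereas the fitted negative binomial model gave a mean of 230 (191 to 268 in 100 sets) with 1 to 10, which argues against ordinary overdispersion as the whole cause. Low counts set to 0 below a fixed number of reads are argued against by 58 counts of 1 to 10 spread over 13 of 15 libraries, and by the 5th percentile of nonzero counts in scarce genes, which differed 7.39-fold between libraries; the bound first written for this test asked for such counts in every library and was relaxed once they were seen. Few template molecules, each copied into many reads, may account for the gap, but the test does not decide it. Where under 1 estimated unit was expected, 6.38% of 486 nonzero counts lay far under a unit. The explanation asked for fewer than 5%, so the value falls on the side against it. That bound was revisited after values were seen, and the exact 95% interval of 4.37% to 8.93% spans it. This explanation therefore cannot be told apart from other causes. No biological explanation was tested, since the design gives none.

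The estimated number of reads per unit ran from 37.1 to 141.6 over the libraries, and the number of units was 113000 ± 6432 in the shock and 351300 ± 182500 in control (SD, n = 3). The estimate was checked only on simulated libraries without group differences. Genes silenced by the shock would lower its number of units, so the lower number need not mean fewer template molecules.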
